A study of Arabidopsis thaliana with 6 samples.

How the data were processed

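Leaf samples came from soil-grown Col-0 plants kept in short days, per the labels. There were 2 H3K27me1 ChIP samples, 2 5mC MeDIP samples and 2 MeDIP input samples, each numbered as biological replicates in the labels. Samples were assigned to groups by these labels. The data used were 2 deposited domain lists, 1 for H3K27me1 and 1 for 5mC. Bowtie (a short-read aligner), SICER (a caller of broad enriched domains) and the TAIR10 build are named, per the submitters' processing notes. Their versions, the calling thresholds, the handling of reads with several matches, the use of the input samples and the pooling of replicates are not given in the sources used here.

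Each line of a deposited list gives a chromosome, a start, an end and a whole-number count of reads in the domain; the authors' read counts are not normalized, and they were used only to describe, rank or split domains within 1 list. Starts count from 0 and ends are the last base, so widths are whole multiples of 300 bp (H3K27me1) and 150 bp (5mC), and positions are printed counting from 1. Domains within a list did not overlap, and the smallest gap between them was 300 bp in both. No domain had fewer than 114 reads (H3K27me1) or 97 reads (5mC). The reads in domains sum to 12706852 for H3K27me1 and 28021211 for 5mC; these sums depend on how much was called and are not the depth of the libraries, which is not used here. Since each list holds 1 value per domain and none per replicate, p-values and intervals measure positions along 1 genome and say nothing about variation between plants.

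Genes came from the RefSeq gene table of assembly TAIR10.1, with 37899 genes on the 5 nuclear chromosomes, of which 27444 were protein-coding and 4843 pseudogenes. All 73 loci of the gene lists were found. The table's assembly carries another name than the build of the lists. The nuclear chromosomes are known to be the same in both, and this was checked: pseudogenes and domains were set against each other at offsets of up to 5000 bp in segments of 5 Mb, and the best overlap lay within 100 bp of offset 0 in 21 of 21 segments for H3K27me1 and 20 of 21 for 5mC (largest offset 150 bp). The check cannot exclude a difference smaller than that. No coordinate of the gene table is printed. The table gives no strand, exons or transposable elements, and no genome sequence was used, so that promoters, exons, transposon families and base composition were not analysed.

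Pericentromeres were defined from the gene table alone. Protein-coding coverage in windows of 100 kb was averaged over 11 windows, and the run of windows around the lowest one with coverage under 0.7 of the chromosome's median was taken. These regions came to 26.9 Mb of 119 Mb, and the remaining 92.2 Mb were called arms. A gene belonged to a region class if more than 50% of it lay there.

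Overlaps were counted in bases. Their null was a circular shift of 1 list by a random offset on each chromosome, on a grid of 50 bp, 100000 times, which keeps widths and spacing; tests within arms or pericentromeres shifted inside the joined region. Tests were two-sided permutation tests with a threshold of 0.05, and the smallest p was 2e-05. A 95% interval came from 10000 bootstrap resamples of blocks of 1 Mb (2000 for differences in reads per kb). A gene was counted as covered if at least 50% of its length, from annotated start to end, lay in domains. The odds ratio of both marks over arm genes used 2000 shifts of the 5mC list (smallest p 0.001) and Fisher's exact test. Each gene list was set against 10000 random lists of protein-coding genes matched on length decile and region class, with Benjamini-Hochberg adjustment over 6 lists and both marks.

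The lists, the tests and the main alternatives were fixed before the data were examined. Named genes follow a rule fixed at the same time: all genes of the lists, the 5 arm genes with the most bases covered by each mark alone and by both, and the 5 widest domains of each list with the genes inside them. The lists were factors of DNA methylation and silencing, Polycomb target regulators, housekeeping reference genes, photosynthesis genes, long constitutively expressed genes, loci known for methylated repeats, and transposon loci. The analysis of pseudogenes, of gene edges, of gene length, of base annotation, of read density at equal width and of the odds ratio in pericentromeres was added after the data were examined.

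The tests were tested on simulated data. Apart from planted ones, simulated domains were placed evenly over the chromosomes, whereas both real lists cluster in pericentromeres. The rates of the shift and odds ratio tests therefore do not show how often they call unrelated lists that are both clustered. With lists of the real widths placed at random, the shift test called 5% of 200 H3K27me1-like lists of 13000 domains against the 5mC domains and 4.5% of 200 5mC-like lists of 12000 domains against protein-coding genes. With 5% of the H3K27me1-like domains planted on 5mC domains, 88% of 50 lists were called. The gene list test called 3% of 100 random lists of 15 genes and 93% of 100 lists in which 33.3% of the genes were covered by H3K27me1. Each simulated gene list was judged by its own p-value, without the Benjamini-Hochberg adjustment used for the real gene lists. The 93% therefore does not show how often the adjusted test would call such a list. The odds ratio test called 3.33% of 60 random lists and 100% of 10 lists with planted genes; a first run on fewer random lists had called a larger share, and the number of lists was raised for that reason.

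Alternatives were domains of at least 1000 bp, domains closer than 600 bp merged, each chromosome left out, the part of each list at or above its median of reads per kb, pericentromeres of 2.5 Mb on each side of the window lowest in gene coverage, shares of domains in place of bases, other gene cutoffs, other matching of random lists and shifts inside windows of 100 kb. The shifts inside windows were added after the data were examined. The split by reads per kb stood in for a score per domain, which the lists do not hold, and was chosen after the data were examined. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.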

Results

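Enrichment of monomethylated lysine 27 of histone H3 (H3K27me1) and of methylated cytosine (5mC) was profiled in young rosette leaves of the Arabidopsis thaliana accession Col-0, the source of the reference genome. H3K27me1 is a histone mark of heterochromatin placed by the methyltransferases ATXR5 and ATXR6. DNA fragments carrying H3K27me1 were collected by chromatin immunoprecipitation (ChIP), and fragments carrying 5mC by immunoprecipitation of methylated DNA (MeDIP). The labels name 2 biological replicates of each, with 2 input samples for the methylated DNA. The analysed data were 1 list of enriched domains per mark, each domain with a position and a number of reads. The H3K27me1 list held 13068 domains with 12706852 reads, and the 5mC list 12238 domains with 28021211 reads. Because each domain had 1 value and none per replicate, no replicate error could be computed. The intervals given are therefore block bootstrap intervals, which cover variation along the genome only.

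The comparison of the marks along the chromosomes asked where in the genome each is enriched. Both lists were concentrated in the pericentromeres, the gene-poor sequence around the centromeres. H3K27me1 domains covered 47.4% of pericentromeric bases and 6.60% of the bases of the chromosome arms. 5mC domains covered 48.9% and 4.40% of the same regions. Pericentromeres, which made up 22.6% of the analysed length, held 67.7% of H3K27me1 bases (95% interval 55.9 to 76.1%) and 76.4% of 5mC bases (65.8 to 83.1%).

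When the domains were shifted along the chromosomes, 23.1% of H3K27me1 bases and 23.2% of 5mC bases fell in pericentromeres on average (permutation p = 2e-05 for each, two-sided, the smallest the shifts can give). The pericentromeric share was 8.70 percentage points higher for 5mC than for H3K27me1 (interval 6.62 to 11.1). Chromosome 4 had the highest pericentromeric coverage for both marks, with 52.5% of bases in H3K27me1 domains and 53.6% in 5mC domains. Chromosome 2 had the lowest H3K27me1 coverage there, 44.0%, against 48.3% for 5mC. The pericentromere of chromosome 2 holds the longest stretch without H3K27me1 domains of any pericentromere, 278.4 kb, which is described under the other observations. On the arms, coverage varied little between chromosomes, from 6.48 to 6.87% for H3K27me1 and from 4.20 to 4.77% for 5mC.

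**Figure D1:**
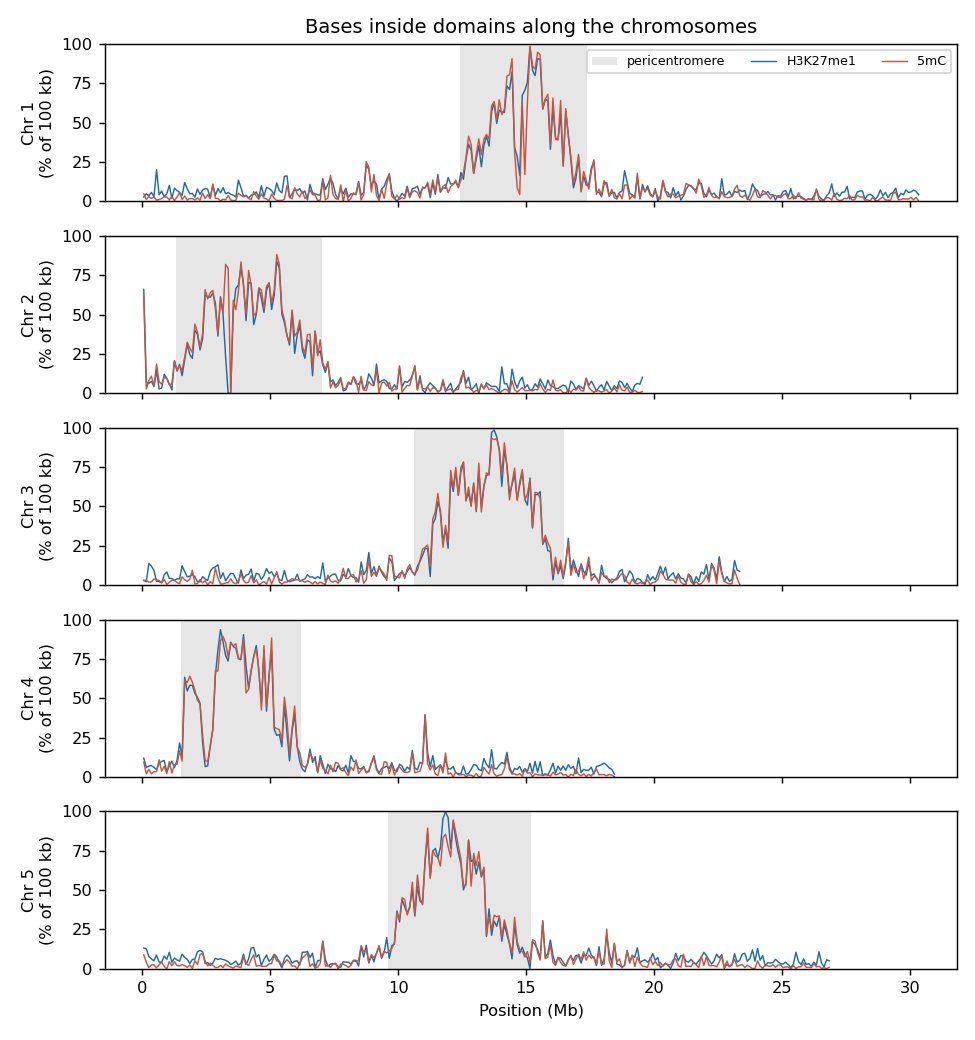
Percent of bases inside H3K27me1 domains (blue) and 5mC domains (red) in 100 kb windows along the 5 chromosomes, with position in Mb on the x axis and pericentromeres shaded. Both lines rise inside the shaded regions, where 47.4% of bases lie in H3K27me1 domains and 48.9% in 5mC domains.

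Domains of both lists were mostly narrow, and the wider ones held most of the sequence. The median width was 600 bp for H3K27me1 (quartiles 600 and 1200 bp) and 450 bp for 5mC (300 and 1200 bp). Domains of at least 1000 bp were 33.0% of the H3K27me1 list and 28.3% of the 5mC list, and they held 74.1% and 79.8% of the covered bases. The 148 and 253 domains of at least 10 kb held 14.0% and 23.5%. In all, H3K27me1 domains covered 18.8 Mb, or 15.8% of the analysed length, and 5mC domains 17.2 Mb, or 14.4%. Widths and numbers of domains depend on the calling windows, which differed between the lists (300 bp for H3K27me1 and 150 bp for 5mC), so that the 2 lists are compared here by position and not by width.

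The overlap of the lists asked whether the marks occupy the same sequence. Most 5mC-enriched sequence was also enriched in H3K27me1: 13.6 Mb lay in both lists. This was 79.3% of 5mC bases (interval 75.0 to 82.2%) and 72.4% of H3K27me1 bases (65.6 to 77.0%). The overlap was nearly complete in pericentromeres, where 89.2% of H3K27me1 bases were in 5mC domains (87.4 to 90.6%). On the arms the value was 37.3% (32.7 to 41.7%), lower by 51.9 percentage points (47.0 to 56.8).

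Shifted lists shared 16.1% of 5mC bases and 14.7% of H3K27me1 bases on average (permutation p = 2e-05 for each, two-sided). Shifts within a region class gave 4.40% of H3K27me1 bases on the arms and 49.0% in pericentromeres, below the observed 37.3% and 89.2% (permutation p = 2e-05 for each). Both lists also share gradients inside a class. Shifts inside windows of 100 kb, which keep local coverage, gave 7.08% on the arms, 61.0% in pericentromeres and 43.6% over the genome (permutation p = 2e-05 for each). Of the 7166 H3K27me1 domains on the arms, 5132 (71.6%) touched no 5mC domain. Of the 5825 arm domains of 5mC, 3884 (66.7%) touched no H3K27me1 domain, although 55.8% of arm 5mC bases lay in H3K27me1 domains (52.3 to 58.9%). The 5mC domains that touched none had a median width of 300 bp, against 750 bp for the arm domains of 5mC with at least 50% of their width in H3K27me1. A wider domain touches the other list more often by chance, and no expectation matched on width was computed for these domains. The share of arm H3K27me1 bases in 5mC domains rose from 37.3% to 61.2% with the part of each list that had more reads per kb. The pericentromeric share was then 84.6%. With domains of at least 1000 bp the shares were 54.4% on the arms and 89.6% in pericentromeres. The size of the difference between the regions thus depends on the narrow and weak domains.

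**Figure D2:**
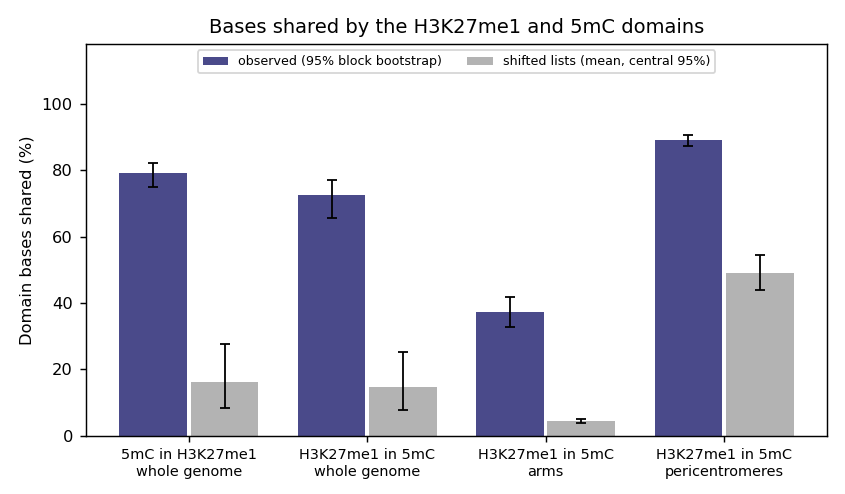
Percent of domain bases shared by both lists (dark bars, error bars 95% block bootstrap intervals) and the mean over shifted lists (grey bars, error bars the central 95% of shifts), over the whole genome and by region. Observed sharing lies above the shifted lists in every panel position, with 37.3% against 4.40% on the arms and 89.2% against 49.0% in pericentromeres.

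Annotated pseudogenes, the class in which the gene table places transposon loci such as EVD, AtMu1 and ONSEN, were heavily covered by both marks. H3K27me1 domains covered 78.3% of pseudogene bases (interval 74.6 to 80.9%) and 5mC domains 78.3% (74.6 to 81.0%). On the arms, away from the pericentromeres, the values were 58.9% (54.8 to 62.7%) and 57.0% (52.5 to 61.1%). There, the sequence outside pseudogenes was covered to 5.29% and 3.10%. Of 4843 pseudogenes, 3504 had at least 50% of their length in H3K27me1 domains, 3492 in 5mC domains and 3294 in both.

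The shifted lists covered 6.59% of arm pseudogene bases with H3K27me1 and 4.42% with 5mC (permutation p = 2e-05 for each, two-sided). The LTR retrotransposon EVD had 81.9% of its annotated length in H3K27me1 and 78.1% in 5mC domains. The DNA transposon AtMu1 was covered to 100% by both marks. The heat-responsive retrotransposon ONSEN had 100% in H3K27me1 and 98.9% in 5mC domains. The class was taken up after the data were examined, since the gene table has no class of transposable elements, and it also holds pseudogenes of other kinds.

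Protein-coding genes on the arms separated the marks. Arm bases in H3K27me1 domains alone lay to 92.8% in protein-coding genes (interval 91.5 to 93.9%), against 64.7% of all arm bases. Bases in 5mC domains alone lay there to 57.9% (55.0 to 60.8%), and bases in both to 27.3% (24.1 to 30.9%), with 50.6% of the latter in pseudogenes. Sequence outside any annotated gene made up 3.42% of the bases with H3K27me1 alone and 34.9% of those with 5mC alone. In pericentromeres, where 4.71% of the bases in both lists were protein-coding, H3K27me1 alone lay to 17.4% in protein-coding genes (12.3 to 24.3%), about the share of all pericentromeric bases (17.9%).

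Shifting the arm bases with H3K27me1 alone gave a protein-coding share of 64.7% on average (permutation p = 2e-05, two-sided). Taking all domains, 5mC covered 2.78% of protein-coding arm bases (interval 2.56 to 3.01%) and 7.39% of the other arm bases, with 4.40% in shifted lists (permutation p = 2e-05); with the part of the list that had more reads per kb the 5mC value was 1.48% against 3.03%. H3K27me1 covered 6.97% of protein-coding arm bases (6.67 to 7.30%) and 5.90% of the others, with 6.60% in shifted lists (permutation p = 2e-05). The small H3K27me1 excess over all domains did not hold up: coverage was below the shifted lists with domains of at least 1000 bp (2.47% against 3.17%) and with the part of the list that had more reads per kb (2.07% against 3.04%). With pericentromeres of fixed width it was 6.99% against 6.96% (permutation p = 0.85).

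**Figure D3:**
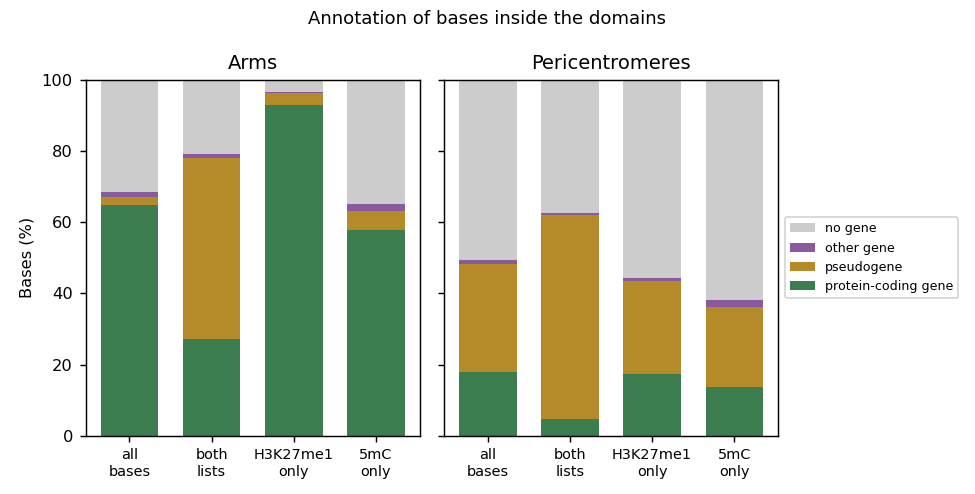
Annotation of the bases inside the domains, in percent, on the arms (left) and in pericentromeres (right), for all bases, bases in both lists and bases in 1 list only. On the arms, 92.8% of bases with H3K27me1 only lie in protein-coding genes and 50.6% of bases in both lists in pseudogenes.

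Around protein-coding genes, both marks were lowest at the gene edges. Among 13478 protein-coding arm genes of at least 2000 bp, H3K27me1 domains covered 0.971% of the last 100 bp outside a gene edge (0.643 to 1.29% over the 5 chromosomes) and 1.25% of the first 100 bp inside (0.847 to 1.67%). Coverage was 8.34% at 800 bp inside (7.52 to 8.86%) and 6.25% at 2000 bp outside (5.55 to 6.82%). 5mC domains covered 0.764% just inside the edge (0.619 to 0.866%), 3.10% at 800 bp inside (2.83 to 3.51%) and 3.41% at 2000 bp outside (3.08 to 3.76%). The edges of 413 arm pseudogenes of at least 2000 bp showed no such minimum. There, H3K27me1 rose from 15.9% at 2000 bp outside to 70.5% at 400 bp inside, and 5mC from 14.4% to 67.0%. Starts and ends of genes were pooled, since the gene table gives no strand.

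**Figure D4:**
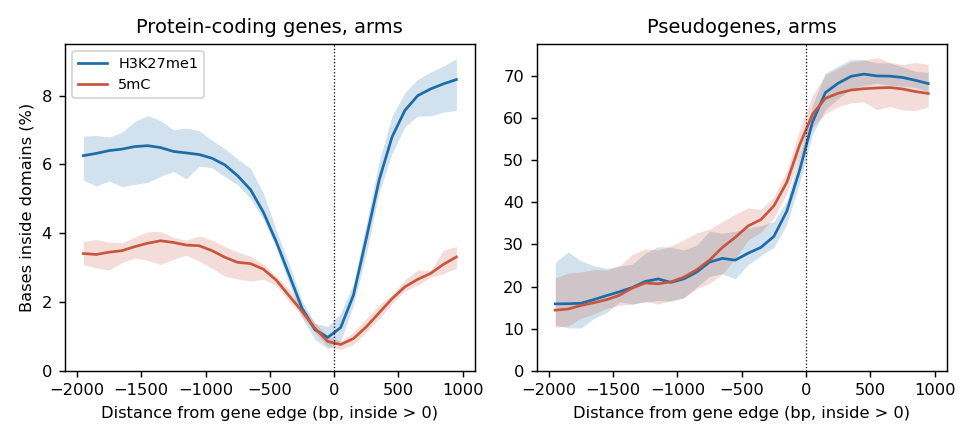
Percent of bases inside H3K27me1 (blue) and 5mC (red) domains by distance from the gene edge in bp, in 100 bp steps, for protein-coding genes (left) and pseudogenes (right) of the arms. Lines are the value over the 5 chromosomes and shading the lowest to highest chromosome. H3K27me1 falls to 0.971% just outside protein-coding gene edges and reaches 70.5% inside pseudogenes.

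The marks also differed by gene length. In the shortest decile of protein-coding arm genes (median 572 bp), H3K27me1 covered 10.2% of bases (interval 8.94 to 11.5%), and in the longest decile (median 5300 bp) 4.97% (4.52 to 5.45%). 5mC covered 6.07% of bases in the shortest decile (5.02 to 7.15%), 2.13% in the fifth decile (1.75 to 2.56%) and 3.22% in the longest (2.84 to 3.62%). The share of genes touched by a 5mC domain was 9.19% in the shortest and 32.1% in the longest decile. For H3K27me1 these shares were 14.1% and 26.6%. A longer gene is touched more often by chance, which the shares of bases avoid.

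**Figure D5:**
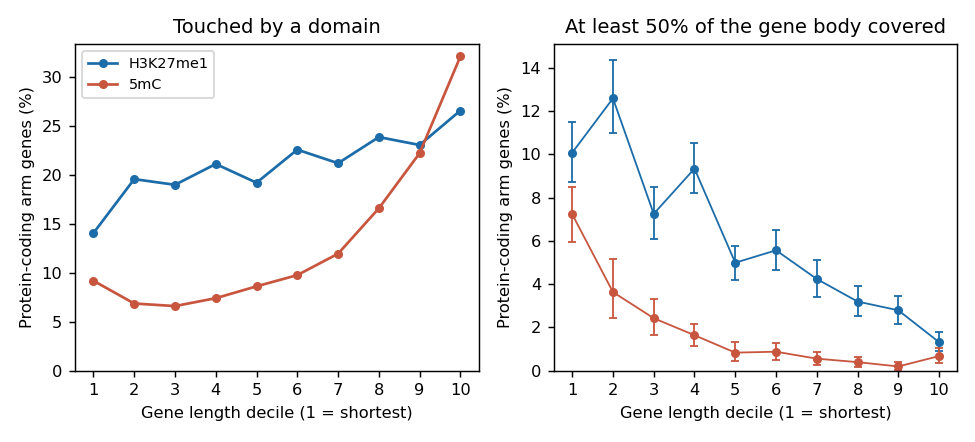
Percent of protein-coding arm genes touched by a domain (left) and with at least 50% of the gene body covered (right), by gene length decile, for H3K27me1 (blue) and 5mC (red). Error bars on the right are 95% block bootstrap intervals. The share touched by 5mC domains is 9.19% in the shortest and 32.1% in the longest decile.

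Whole gene bodies were rarely covered. Of 25017 protein-coding genes on the arms, 1535 (6.14%, interval 5.68 to 6.60%) had at least 50% of the gene body in H3K27me1 domains and 463 (1.85%, 1.53 to 2.21%) in 5mC domains. Both marks met on 325 genes, 70.2% of those covered by 5mC and 21.2% of those covered by H3K27me1. A further 1210 genes reached this level for H3K27me1 but not for 5mC, and 138 for 5mC but not for H3K27me1. Genes below the level can still hold domains of that mark. Immunoprecipitation of methylated DNA depends on the density of CG dinucleotides, which was not analysed here, so that sparse 5mC could go uncalled. Counting all 27444 protein-coding genes, 2090 were covered by H3K27me1 and 1013 by 5mC, and with any overlap of at least 1 bp the counts were 6132 and 4281. Of the 2427 pericentromeric genes, 555 were covered by H3K27me1, 550 by 5mC and 442 by both.

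The odds ratio of both marks on the same arm gene was 45.3 (95% interval 36.8 to 55.8, which treats genes as independent). Shifted 5mC lists gave 1.14 on average (permutation p = 0.001, two-sided, the smallest these shifts can give; Fisher's exact p = 9.99e-292, which also treats genes as independent). In pericentromeres the odds ratio was 63.4 (47.8 to 84.1), with 1.02 in shifted lists (permutation p = 0.001). The size of the odds ratio depends on the cutoff: with any overlap of at least 1 bp it was 2.70, and with at least 80% of the gene body covered it was 192.

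Gene lists fixed before the data were examined set named loci beside these totals. Genes of photosynthesis lay outside both lists: none of the 10, among them RBCS1A (the small subunit of Rubisco), LHCB1.1 (a chlorophyll-binding protein) and RCA (Rubisco activase), had a base in either. Of the 10 housekeeping reference genes, such as ACT2 and UBQ10, PP2AA3 alone was touched, with 3.39% of its length in 5mC domains. Of the 14 Polycomb target regulators, none had 5mC and LEC1 alone had H3K27me1, over 14.5% of its length; FLC (the flowering repressor), AG and STM had neither.

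Of the 18 factors of DNA methylation and silencing, 8 were touched by H3K27me1 and 7 by 5mC. RDR2, the RNA polymerase that makes double-stranded RNA for small interfering RNAs, had 71.7% of its length in H3K27me1 and 28.7% in 5mC domains. NRPD1, the largest subunit of RNA polymerase IV, had 45.5% and 11.4%. NRPE1, the corresponding subunit of RNA polymerase V, had 38.9% in H3K27me1 and 0% in 5mC domains. The DNA demethylase ROS1 had 26.1% and 2.17%. The methyltransferases CMT2, CMT3 and DRM2 and the remodeller DDM1 had no base in either list, and MET1 had 9.44% in H3K27me1 alone. The H3K27 monomethyltransferase ATXR6 had 14.6% in H3K27me1 domains, and ATXR5 had 0%.

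Of the 12 long constitutively expressed genes, 11 were touched by 5mC domains and 3 by H3K27me1 domains. NRPB1, the largest subunit of RNA polymerase II, had 35.7% of its length in 5mC and 0% in H3K27me1 domains, and DCL1, which makes microRNAs, had 27.8% and 3.70%. SPT6L had 14.8% in 5mC domains and 0% in H3K27me1 domains, while AGO1 had neither. Among the 6 loci known for methylated repeats, SDC had 31.2% in H3K27me1 and 12.4% in 5mC domains, FWA 14.6% and 5.87%, and QQS 17.4% and 17.4%. MEA, PHE1 and FIS2 had no covered base.

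No list stood apart from random lists of protein-coding genes matched on length decile and region class after Benjamini-Hochberg adjustment over 12 tests. For some short lists low coverage could not pass at all. With 0% in H3K27me1 domains, the photosynthesis genes had permutation p = 0.16 and the housekeeping reference genes permutation p = 0.12. For such lists the test cannot tell low coverage from that of other genes. The long constitutively expressed genes had a mean 5mC coverage of 10.1%, against 3.18% in random lists (permutation p = 0.061, adjusted p = 0.3). The factors of DNA methylation and silencing had a mean H3K27me1 coverage of 12.5%, against 5.75% (permutation p = 0.074, adjusted p = 0.3). The Polycomb target regulators had 1.03% in H3K27me1, against 7.07% (permutation p = 0.11, adjusted p = 0.3). The 3 transposon loci are pseudogenes in the table and were not tested.

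The arm genes with the most bases in H3K27me1 domains and none in 5mC domains included the transporters ABCC4 (4200 bp, 70.6% of the gene), ABCB12 (3600 bp, 72.0%) and ABCG40 (3600 bp, 55.7%), besides AT1G50820 (4200 bp, 58.7%) and NRPE1. The genes with most 5mC and no H3K27me1 were UBQ13, a ubiquitin gene (4758 bp, 100%), the disease resistance gene RPP4 (3085 bp, 41.8%), NRPB1 (2700 bp, 35.7%), AT3G56410 (2400 bp, 46.4%) and CSLD3 (2250 bp, 45.6%), which acts in root hair growth. Most bases in both were found in AT5G39770 (8049 bp), AT1G58602 (6000 bp), AT1G27570 (5939 bp), AT4G22410 (5543 bp) and AT3G60950 (5400 bp).

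The widest H3K27me1 domains all lay in pericentromeres, and 3 of the 5 held pseudogenes and no protein-coding gene. The widest H3K27me1 domain was on chromosome 5 from 11803501 to 11925600 (TAIR10), 122.1 kb with 1151 reads per kb, and held 14 pseudogenes and no protein-coding gene; 85.5% of it was in 5mC domains. The next widest were on chromosome 5 from 12007201 to 12065700 (12 pseudogenes), on chromosome 4 from 3958801 to 4015200 (6 pseudogenes) and from 2910601 to 2965500 (4 pseudogenes and 1 protein-coding gene), and on chromosome 3 from 13681201 to 13736100 (no annotated gene). Between 81.4% and 94.5% of these 4 domains was in 5mC domains.

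The widest 5mC domain, on chromosome 2 from 3281551 to 3379350, spanned 97.8 kb with 2493 reads per kb and had no base in H3K27me1 domains. It overlapped 30 protein-coding genes, 18 pseudogenes and 6 tRNA genes. Its neighbour on chromosome 2 from 3238651 to 3281250 (42.6 kb) overlapped 21 protein-coding genes and had 0.352% of its bases in H3K27me1 domains. The other 3 of the 5 widest 5mC domains lay almost wholly in H3K27me1 domains. They were on chromosome 1 from 15454651 to 15511800 (14 pseudogenes, 96.3% in H3K27me1), on chromosome 1 from 15087151 to 15139050 (no annotated gene, 99.7%) and on an arm of chromosome 2 from 1051 to 41700, over 2 ribosomal RNA genes, 6 pseudogenes and 3 protein-coding genes (99.3%).

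Read density within the lists was compared at equal domain width, since narrow domains need more reads per kb to be called. Arm H3K27me1 domains of 600 bp wholly inside 5mC domains had a median of 448 reads per kb (250 domains), against 378 for those outside 5mC (1751 domains), a difference of 69.2 (interval 43.3 to 86.7). In pericentromeres the difference was 119 (100 to 143). Arm 5mC domains of 600 bp inside H3K27me1 domains had 1121 reads per kb and those outside 968, a difference of 153 (21.7 to 278). At 300 bp the arm difference for 5mC was 75.0, with an interval from -13.3 to 180. In pericentromeres the 5mC difference was 183 at 600 bp (40.0 to 318) and -122 at 900 bp (-432 to 210). The read numbers are the authors' own, are not set against input reads, and are not compared between the lists.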

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

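Of 162 alternative values for the main results, 150 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. Alternatives added after the data were examined were those for pseudogenes and for bases with H3K27me1 alone, the split by reads per kb, shifts inside windows of 100 kb, the extension of genes on both sides, and the removal of the longest pericentromeric gap. The sharing of sequence by the lists, the pericentromeric shares, the pseudogene coverage and the odds ratio kept their call under every alternative run. The share of 5mC bases in H3K27me1 domains ranged from 52.1% (as a share of domains) to 83.7%. The protein-coding share of arm bases with H3K27me1 alone ranged from 83.5 to 93.2%. The odds ratio ranged from 2.70 to 694. Leaving out any 1 chromosome changed no call.

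The coverage of protein-coding arm bases by H3K27me1 did not keep its call. It was below the shifted lists, in place of above, with domains of at least 1000 bp (2.47%) and with the part of each list with more reads per kb (2.07%), and with pericentromeres of fixed width (6.99%) the difference did not pass the threshold. The cause was not tested. Counts of covered genes moved with the cutoff. For H3K27me1 they were 6132 with any overlap, 786 at 80% of the gene body, 539 with genes extended by 1000 bp on both sides, 1005 with domains of at least 1000 bp and 984 with the part of the list with more reads per kb, against 2090. For 5mC they were 4281, 674, 545 and 655 under the first 4 of these, against 1013. Fewer domains or a stricter cutoff lower such counts by construction.

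No gene list passed the threshold under any matching (0 of 12 tests in each). As a share of genes with at least 50% covered, low values could not pass, since random lists often held no such gene. Non-significant list means changed side of their random mean in 4 cases: 5mC on the silencing factors was 0% as a share of genes with at least 50% covered and 3.57% with matching on region only, 5mC on the long genes was 0% as such a share, and H3K27me1 on the loci of methylated repeats was 10.5% with matching on region only. Domains lay within 1000 bp of 9 of 18 silencing factors for H3K27me1 and 7 for 5mC.

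No paired analysis was possible because the domain lists hold no value per replicate, although the labels give the groups the same replicate numbers; a replicate block and leaving out a replicate could not be run for the same reason. Transposable elements, base composition and an extension upstream of genes were not run, since they need annotation or sequence not used here. Library totals and input reads were not used here, so that weak domains could not be graded against background, and domains under the callers' thresholds are not seen. The labels give input samples for the MeDIP alone and no control for the H3K27me1 ChIP. The H3K27me1 coverage of gene bodies and gene edges was therefore not set against chromatin background.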

Other observations

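The tests of families, of the longest gap, of background over expressed genes and of domains with very many reads were chosen after the result was seen; those of random weak calls and of 5mC domains beside H3K27me1 domains were chosen before their values were computed. Families of arm genes sharing a symbol stem, with at least 10 members, were compared by the share of members with at least 50% of the gene body covered. Of 300 Fisher's exact tests over 150 families and both marks, 2 passed Benjamini-Hochberg adjustment, both for H3K27me1, and 1 of them is described here. Heat shock protein genes (HSP) had 7 of 18 members covered, 38.9% against 6.14% of all arm genes (exact p = 5.6e-05, adjusted p = 0.011). Coverage depends on gene length, and matched on length decile the expected share was 6.37% (exact p = 4.4e-05, adjusted p = 0.0066); of 2 families passing with this matching, it was the only one that also passed without. None of the 7 was covered by 5mC; they were HSP70T-2, HSP70, HSP17.4, HSP23.6-MITO, HSP21, HSP17.6II and HSP90.1. Genes of a family are not independent, and some lie next to each other.

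A tandem array of tRNA genes on chromosome 1 had 5mC without H3K27me1. From 21268801 to 21306300 (TAIR10), 19 5mC domains with a median of 873 reads per kb touched 19 of 26 tRNA-Ser genes and 1 of 50 tRNA-Tyr genes, and no H3K27me1 domain lay there. The array was picked for this difference, so no test of it is given. Outside this array, no tRNA gene of the arms lay in a domain of either list.

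The longest pericentromeric gap in the H3K27me1 list lay on chromosome 2 from 3238801 to 3517200, 278.4 kb against 66.6 kb for the next longest, in a region known to hold an insertion of mitochondrial DNA. 5mC domains covered 52.7% of it, while 124.2 kb from 3379351 to 3503550 had no domain in either list. The covered 52.7% argues against a failure to place reads as the cause over that part, if reads of both lists were placed by the same rules; for the 124.2 kb it stays open. Reads from organelle copies of the sequence may add to the 5mC domains, whose 2411 reads per kb lay at percentile 92.8 of 723 other pericentromeric 5mC domains of at least 5 kb, too near the upper range to exclude this and short of the 95th percentile set for it. Whether the stretch carries 5mC without H3K27me1 in chromatin thus stays open, and no biological explanation was tested.

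H3K27me1 domains of the arms outside 5mC domains lay almost wholly in protein-coding genes. Calls spread at random would show the protein-coding share of all arm bases outside 5mC domains, 65.8%. In the part of the list with more reads per kb the share was 88.3% (interval 85.6 to 90.7%). That part held 0.975 of 3.82 Mb and does not bear on the weaker calls. Over all arm bases with H3K27me1 alone, weaker calls included, the share was 92.8% (91.5 to 93.9%). This argues against random weak calls as the main source. A 5mC domain just beside these H3K27me1 domains is argued against by the 4.72% of the 5132 domains that had one within 500 bp. The possibility of 5mC below the calling threshold stays open. A background over highly expressed genes also stays open: none of 20 photosynthesis and housekeeping genes was touched, but the lists were pooled after this was seen, so the permutation p of 0.011 decides nothing. Other background may contribute, and no biological explanation was tested.

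A few domains held very many reads. The 5mC list reached 38853 reads per kb on chromosome 2 from 7190851 to 7191600, over AT2G16586 and outside H3K27me1 domains, and 31562 on chromosome 3 from 14189701 to 14209050, over ribosomal RNA genes. The highest H3K27me1 value, 6461 reads per kb, was on chromosome 4 from 3948901 to 3956100. Many copies of a sequence placed on few reference positions could raise both lists at the same places: 13.7% of the 131 H3K27me1 domains with most reads per kb overlapped such a 5mC domain, against 1.92% of random H3K27me1 domains of like width and region class, with a highest value of 6.11% in 1000 draws. This cannot be told apart from stronger enrichment of both marks without input reads, and the labels give input samples for the MeDIP alone.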
